A study of Homo sapiens with 22 samples.

How the data were processed

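Chromatin profiles by CUT&RUN were made from H1-derived trophoblast cells in 22 samples, grouped by the sample titles. Nothing in the labels says whether the samples of a group came from separate cultures. The groups were FLAG profiles of empty-vector and H2A.J-overexpressing STB and TSC, H2A and H2A.J profiles of overexpressing cells, and IgG, Ser2P and serine 5 phosphorylation profiles of shControl and shH2AJ STB. Each group had 2 samples except the pair for serine 5, with 1 each. The empty-vector, IgG, H2A, H2A.J and serine 5 samples were not analysed here.

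Per the submitters' processing notes, Trimmomatic, Bowtie2, SAMtools, MACS2 and bedtools were used on the hg38 build, with no versions or settings given. The 2 FLAG lists hold peak positions and a deposited score that is 0 in every row, so their peaks could be ranked only by width. Their peaks carry region numbers that skip, so they are a selection by the authors from a longer list. How it was made, and how the empty-vector samples entered, is not given in the sources used here. The 2 Ser2P lists are in the layout of the irreproducible discovery rate (IDR) tool, which joins the peaks of 2 samples and keeps those that rank alike. The deposited signal of a peak is the sum of the peak values of the 2 joined lists, as found from the files. The −log10 IDR values deposited by the authors have a minimum of 1.30, which corresponds to an IDR cutoff of 0.05, and a scaled score of up to 1000 is deposited beside them. The peak values are the authors' own and were used to describe, rank or filter peaks within a list. The median values of the 2 joined lists were 7.27 and 8.49 in shControl and 9.64 and 8.83 in shH2AJ. Their Spearman correlation across the listed peaks was 0.232 in shControl and 0.0848 in shH2AJ. The listed peaks were already selected for ranking alike, and the lowest summed value was 10.8 in shControl and 13.5 in shH2AJ, so these correlations do not measure how well the samples agreed. Which joined list belongs to which replicate is not given. Selection by IDR and by a cutoff means that a peak missing from a list can be present below the cutoff. It also means that the number of peaks depends on the depth and the agreement of both samples. Depth was not given in the files, so no depth correction was possible.

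Coordinates were used with GENCODE 44 (Ensembl 110) on hg38, after the peak ends were checked against its chromosome lengths, and are given 1-based. Peaks on chromosomes 1 to 22 and X were kept, which removed 1 STB FLAG peak, and overlapping or touching peaks were merged. Locations were assigned in the order gene start (1 kb on either side), gene end (1 kb), exon, intron and intergenic, using 19962 protein-coding genes. Each list was compared with 100 random placements of the same widths on the same chromosomes outside assembly gaps. Peaks were called shared at an overlap of 1 bp or more. A gene had a peak if one overlapped the gene or 2 kb on either side, so a peak may count for neighbouring genes. Gene lists were set against 10000 random lists of the same size, matched on 10 strata of gene length for FLAG and for the presence of Ser2P, and of shControl covered length for absence from shH2AJ. Percentiles describe these lists and are not tests between conditions, because genes are not replicates. Percentile limits of 2.5 and 97.5 were used for the loss of Ser2P at FLAG genes. Gene lists were called by a Benjamini-Hochberg adjusted tail share under 0.05, for FLAG, for presence of Ser2P in each list and for absence from shH2AJ. The floor for a count of 0 was 3 counts. Intervals of shares are 95% Wilson intervals, and those of the X to autosome ratios are exact binomial ones.

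The genes named were chosen by a rule set before the data were examined. They were H2AJ and 13 textbook STB genes, and the 10 genes per list with the highest peak value or, for FLAG, the largest covered length. The 10 genes with the largest covered length in shControl only and in shH2AJ only were added, with up to 4 genes per gene list. Further members of gene lists are named where a count is broken down, as chosen after their values were seen. The 22 gene lists, with 484 entries, were also fixed before the data were examined. The presence of Ser2P peaks at these lists in shControl and in shH2AJ was compared afterwards.

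Alternatives covered windows, overlap rules, peak subsets, lists of equal length, gene annotation and matching. Sequence motifs were searched as consensus strings on both strands in the FLAG peaks and in 20 control sets matched on chromosome, width and GC content within 2 percentage points. The overlap counts were equal to those of bedtools 2.31.1 for 16 of 16 pairs of lists. A planted overlap of 1000 peaks was found as 1007. On simulated loss of Ser2P over 3924 genes, 8 of 100 null simulations fell outside the percentile limits, 3 of them above. For gene lists of 20 among 19962 genes, 6 added members passed the upper percentile limit, without adjustment, in 100 of 100 simulations, against 2 of 100 with none added. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.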

Results

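CUT&RUN, in which a nuclease tethered by an antibody releases the DNA around a chromatin protein for sequencing, was performed on 22 samples of trophoblast cells derived from the H1 human embryonic stem cell line. Syncytiotrophoblast (STB) is the fused, hormone-secreting layer of the placenta, and trophoblast stem cells (TSC) are its dividing precursors. H2A.J is a variant of the core histone H2A. The samples formed 12 groups, 10 of them with 2 samples and 2 of them with 1 sample. FLAG-tagged H2A.J was profiled with an anti-FLAG antibody in STB and in TSC, beside empty-vector cells. RNA polymerase II phosphorylated on serine 2 of its tail (Ser2P), the elongating form, was profiled in STB carrying a control short hairpin RNA (shControl) or a hairpin against H2A.J (shH2AJ). The comparisons rest on 4 peak lists on the hg38 genome, each made from the 2 samples of its group. There was therefore 1 list per condition, and numbers of peaks, overlaps and genes have no spread between replicates. The files give no read counts, so the depth behind each list is unknown. The 95% Wilson intervals cover counting error only.

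The first question was where FLAG-tagged H2A.J lay in the STB genome. The list held 5202 peaks, of which 5201 lay on the main chromosomes, covering 2.43 Mb with a median width of 436 bp. Most were far from gene starts, at a median distance of 81.9 kb from the nearest protein-coding start. The mean over random placements was 92.3 kb, with a range of 85.5 to 99.2 kb. Of the peaks, 50.9% (49.5 to 52.2%) were intergenic and 38.0% (36.7 to 39.3%) intronic, against 53.8% and 37.9% of randomly placed intervals. Gene starts were over-represented. The windows of 1 kb on either side held 265 peaks, or 5.10% (4.53 to 5.73%), which was 3.37 times the random mean of 1.51%. With windows of 3 kb, the fold was 1.83. Gene ends held 44 peaks, or 0.846% (0.631 to 1.13%), against a random mean of 1.45%. With all annotated genes in place of protein-coding genes, an alternative added after the data were seen, 8.77% of the peaks lay at starts, 1.94 times the random mean of 4.52%, and 32.2% between genes against 36.4% at random.

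**Figure D1:**
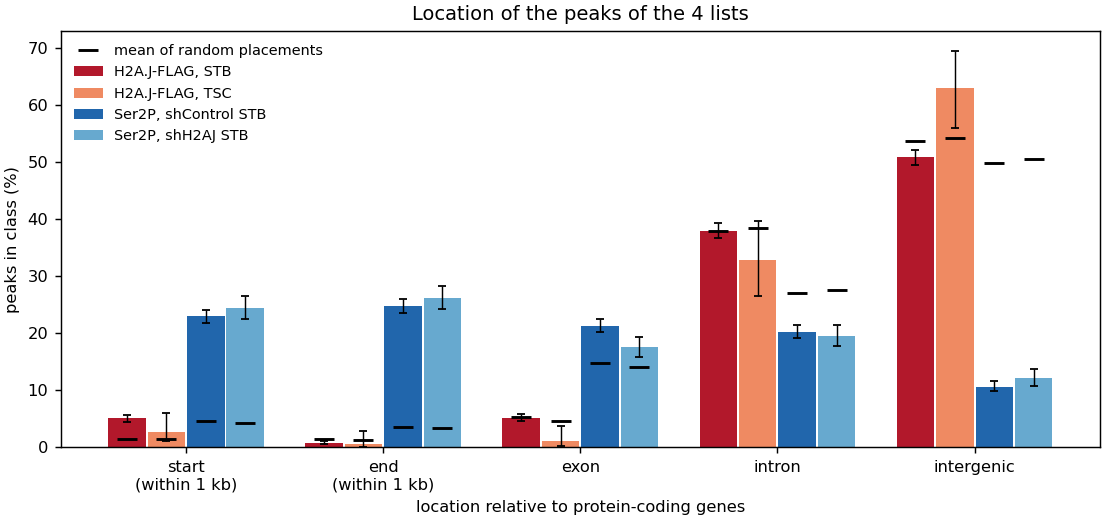
Bars give the percentage of the peaks of each list in each location class relative to protein-coding genes, error bars the 95% Wilson interval, and black dashes the mean of 100 random placements. The Ser2P lists stood above random at gene starts and ends, while 5.10% of the STB FLAG peaks lay at starts against 1.51% at random.

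In all, 2135 of 19962 protein-coding genes had an STB FLAG peak within the gene or 2 kb of it. The most covered length was at RUNX1, a transcription factor gene on chromosome 21 (34787801 to 36004667), with 10 peaks over 6239 bp. The widest of them, at 35293866 to 35295152, was intronic by the annotated span of the gene. All Ser2P peaks at RUNX1 ended by 34892592, toward the gene end, so most of its FLAG peaks lay upstream of them. PDE4D, which encodes a cyclic AMP phosphodiesterase, had 9 peaks over 4345 bp. NRXN3 had 7 peaks, and MACROD2, MAGI2, MAML3 and DAB1 had 6 each. EYS and ZNF385D had 5 peaks, and FHIT had 4. These 10 genes are long, from 437432 bp at MAML3 to 2057829 bp at MACROD2, and long genes take more peaks by chance. The textbook STB genes looked up by rule had no FLAG peak. These were the hormone genes CGA, CGB3, CGB5, CGB8 and CSH1, the fusion genes ERVW-1, ERVFRD-1 and GCM1, and PSG1, CYP19A1, HSD3B1, SDC1 and PGF. H2AJ itself had none. Most of these genes are short. Random lists matched on gene length gave means of only 0.342 of 21 STB hormone genes and 0.463 of 10 pregnancy-specific glycoprotein genes. Absence at such genes is therefore within chance.

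No gene list was over-represented among the FLAG genes after adjustment. Of the 22 lists, 0 passed a Benjamini-Hochberg adjusted tail share of 0.05 among 10000 random lists matched on gene length, and 1 had an unadjusted tail share under 0.05. That list was nutrient transport, with 6 of 21 genes against 2.43 expected, at percentile 98.6. Its unadjusted tail share was 0.045 and its adjusted one 0.935. The 6 genes were the glucose transporter genes SLC2A1 and SLC2A3, the cystine transporter gene SLC7A11, the lipid transporter gene ABCA1, the drug efflux gene ABCG2 and the fatty acid receptor gene CD36. At SLC2A1 on chromosome 1, the peak spanned 42940867 to 42941182 in an intron. Other STB markers had 4 genes with a peak, FLT1, PAPPA2, SERPINB2 and TENT5A, against 3.01 expected. TSC and cytotrophoblast markers also had 4, EGFR, LRP2, MYC and WWTR1, against 4 expected. Hypoxia genes had 3, EGLN3, HK2 and SLC2A1, against 1.94. Amnion markers had 2, TNC and VTCN1, against 0.953. Extravillous trophoblast (EVT) markers had 2, FSTL1 and ITGA1, against 2.40. Replication-dependent histones had 2, H2BC4 and H4C3, both from the same peak, against 0.493. Ribosomal protein genes also had 2, RPS26 and RPS27A, against 1.69. A single gene had a peak in each of 7 lists. These were DYSF (trophoblast fusion), MCM3 (cell cycle), TP53 (senescence and p53), IFIT1 (inflammatory and interferon), KCNQ1 (imprinted), MACROH2A2 (H2A variants and replication-independent histones) and AFF1 (transcription elongation). None was found among STB hormones, pregnancy-specific glycoproteins, steroidogenesis, trophoblast transcription factors, pluripotency, germ layer or cytoskeleton genes.

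The second question was whether H2A.J-FLAG took the same sites in TSC. The TSC list was much shorter, with 192 peaks over 0.0590 Mb and a median width of 266 bp. Of these, 46 overlapped an STB FLAG peak (24.0%, 18.5 to 30.5%), against a mean of 0.220 and at most 2 for random placements. The shared sites were 0.884% of the STB list (0.664 to 1.18%). A reciprocal overlap of 50% left 28 shared peaks, and the wider 50% of both lists shared 15. In TSC, 63.0% of the peaks were intergenic, above all random placements (mean 54.2%, range 45.3 to 61.5%). At gene starts lay 5 peaks, or 2.60% (1.12 to 5.95%), within the range of random placements (mean 1.44%, range 0 to 4.69%). A TSC peak was present at 75 genes, of which 41 also had an STB peak. At ALPK2 on chromosome 18, a peak at 58628989 to 58629437 lay at the gene start and was shared between the cell types. An intron in the annotated span of CFTR, which encodes a chloride channel, held a shared peak on chromosome 7 at 117401564 to 117401774. The nearest gene start to this peak was that of ASZ1, at 26.45 kb. SLC30A8, a zinc transporter gene, also held a shared peak, at 117172009 to 117172449 on chromosome 8. Of the other genes with the most TSC covered length, PCDH9 and GRM8 also had STB peaks within the gene window. MSRA, CSRNP3, PSMB2, LINC02210-CRHR1 and TBCEL had none. No TSC peak overlapped a Ser2P peak of either STB list, which allows a share of up to 1.56% by a floor of 3 counts. Random placement gave means of only 1.40 (0 to 5) and 0.570 (0 to 3) overlaps, so a count of 0 is within chance. The lists differ in length, and no test of the difference between cell types was possible with 1 list each.

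The third set of measurements was of elongating polymerase in shControl STB. The list held 4868 merged peaks over 21.2 Mb with a median width of 3192 bp. Of these, 24.8% lay at gene ends, 6.83 times the random mean, 22.97% at gene starts and 10.7% between genes, against 49.8% between genes at random. In all, 3924 genes had a peak. The highest peak value, as the authors deposited it, was 244.5 at EPAS1, which encodes the hypoxia-inducible factor HIF-2α. That peak spanned 46298875 to 46396828 on chromosome 2. It was followed by FLNB (214), an actin crosslinker gene, the 14-3-3 gene YWHAZ (127), the death receptor gene TNFRSF21 (118) and the myosin gene MYH9 (112). FRMD6 (110), SESN3 (108), GPRC5A (87.4), GRAMD2B (84.4) and the integrin gene ITGB6 (83.7) completed the 10 highest.

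Several gene groups carried shControl Ser2P peaks more often than random lists matched on gene length, in a comparison added after the data were seen. Ribosomal protein genes had a peak at 55 of 79, against 14.2 expected. Cytoskeleton and brush border genes had 12 of 17 against 3.47, including FLNB, MYH9, ACTN1 and ACTN4. Hypoxia genes had 9 of 18 against 3.52, and transcription elongation genes 12 of 26 against 5.32. H2A variants and replication-independent histones had 6 of 10 against 1.64. TSC and cytotrophoblast markers had 11 of 25 against 4.92, including the keratin genes KRT7 and KRT8, the integrin gene ITGA2 and TEAD1. These 6 groups had an adjusted tail share under 0.05 among the random lists, with percentiles of at least 99.7. Markers of amnion, a cell type that can arise in trophoblast derivations, had 5 of 12 against 2.41 (percentile 95.3). Their adjusted tail share was 0.264, so this list did not pass. ITGB6 was covered over 90.9 kb and VTCN1 over 26.0 kb, while 7 of the 12 had no peak in either Ser2P list. Trophoblast transcription factors had 9 of 22 against 4.31 (percentile 98.9), senescence and p53 genes 8 of 17 against 3.39 (percentile 99.3) and nutrient transport genes 9 of 21 against 4.41 (percentile 98.8). Replication-dependent histones had 10 of 42 against 5.53.

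The lists of STB hormones and of other STB markers were near the expected number. STB hormones and secreted factors had 4 of 21 against 3.35, at percentile 66.3, and other STB markers had 5 of 23 against 4.49, at percentile 61.9. The pregnancy-specific glycoprotein genes, near-identical copies among which reads can be misplaced, had 0 of 10 against 2.12, at percentile 4.61. Among the textbook STB genes, only HSD3B1, which encodes a progesterone-synthesis enzyme, had a shControl peak. It lay at the gene end with a value of 10.9, close to the lowest value of the list, 10.8. HSD3B1 was covered over 2.01 kb in shControl and 4.86 kb in shH2AJ. The shControl peak began at 119515043 and the gene ended at 119515054, so nearly all of that coverage was in the 2 kb flank. In shH2AJ its peak had a value of 14.2, also close to the lowest value of that list, 13.5. CGA, CGB3, CGB5, CGB8, CSH1, PSG1, ERVW-1, ERVFRD-1, GCM1, CYP19A1, SDC1 and PGF had no peak in either Ser2P list. A gene without a listed peak can still carry Ser2P below the authors' cutoff. Whether reads could be placed uniquely at these genes was not examined. EVT markers had 5 of 20 against 3.96. Germ layer markers had 0 of 16 against 2.92, at percentile 2.03, and cell cycle genes 2 of 25 against 5.22, at percentile 5.11. Their adjusted tail shares were 0.169 and 0.278. Fusion genes had 2 of 16 against 3.18, steroidogenesis genes 2 of 12 against 2.41 and pluripotency genes 2 of 15 against 2.92. Imprinted genes had 2 of 17 against 3.31 and inflammatory genes 3 of 22 against 4.05.

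The fourth comparison asked how Ser2P peaks differed after H2A.J knockdown. At H2AJ on chromosome 12 (14774405 to 14778002), the shControl list had a peak at the gene end, 14776242 to 14778171, with a value of 11.1. Another, 14762036 to 14772529 with a value of 30.8, lay upstream and reached the gene's flank. The shH2AJ list had no peak there. Hairpins act on the transcript, so Ser2P peaks do not measure the knockdown. Across the genome, the shH2AJ list was shorter, with 1819 peaks over 7.50 Mb, and the shControl list had 2.68 times as many peaks. Of the shControl peaks, 1311 (26.9%, 25.7 to 28.2%) overlapped a shH2AJ peak and 3557 did not. Of the shH2AJ peaks, 1408 (77.4%, 75.4 to 79.3%) overlapped a shControl peak and 411 did not. Random placement gave a mean of 27.6 shared shControl peaks. With the 2 lists held to equal length by peak value, 943 peaks were in shControl alone and 794 in shH2AJ alone, counts that equal lengths hold near each other. Of the shH2AJ peaks, 24.5% lay at starts, 26.2% at ends and 12.2% between genes. The share in exons was 17.6% (15.9 to 19.4%) in shH2AJ and 21.3% (20.2 to 22.5%) in shControl, against random means of 14.2% and 14.8%. The intervals do not overlap, but they cover counting error within 1 list each and not spread between samples. This difference was not tested.

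Overlap rose with peak value. In the lowest 10% of shControl peaks by value, 8.21% overlapped a shH2AJ peak, and in the highest 10%, 71.0% (66.8 to 74.9%) did. Peak width rose along with value, from a median of 1849 bp to 10160 bp, and wider peaks overlap more readily. By gene, 1439 genes had a peak in both lists, 2485 in shControl only and 225 in shH2AJ only. Thus 63.3% (61.8 to 64.8%) of shControl genes had no shH2AJ peak. Where both lists had one, the covered length was smaller in shH2AJ at 1219 genes and larger at 217, with a median log2 ratio of -0.75. With lists of equal length, 899 genes were in shControl only and 584 in shH2AJ only. With 1 list per condition and unknown depth, these differences have no replicate check. The lowest listed peak value also differed, at 10.8 in shControl and 13.5 in shH2AJ. Weak peaks could thus be listed in shControl and not in shH2AJ. Part of the difference in peaks, genes and covered length can come from this. How much was not tested, because peak values were used only within a list.

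**Figure D2:**
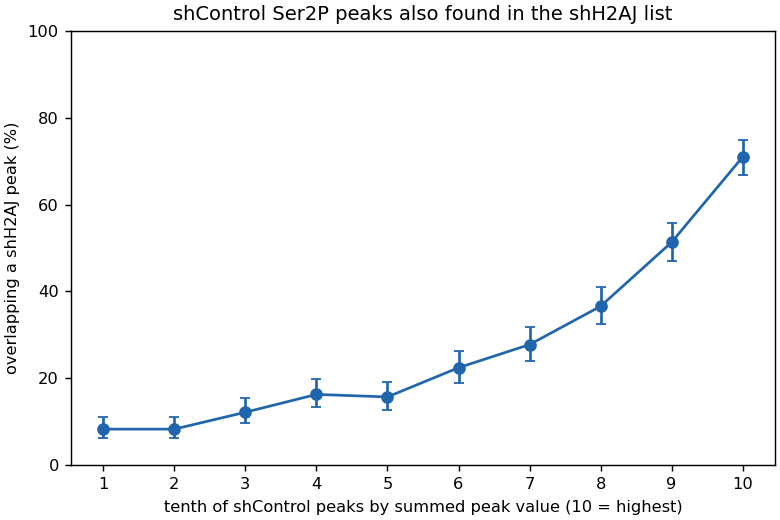
Points give the percentage of shControl Ser2P peaks that overlap a shH2AJ peak, in 10 equal bins of peak value, with 95% Wilson intervals. The percentage rose from 8.21% in the lowest bin to 71.0% in the highest.

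The widest coverage present in shControl only was at COL4A1, a basement membrane collagen gene, with 11 peaks over 31.8 kb. SEMA5A followed with 30.5 kb, the histone demethylase gene KDM4B with 26.6 kb and the actin-disassembly gene WDR1 with 26.6 kb. PMEPA1, PTK7, DUSP10, BMP1, TBL1XR1 and NEK6 completed the 10. Some of their peaks, with values down to 11.6 at COL4A1 and 11.4 at PTK7, lay under 13.5, the lowest value listed in shH2AJ. The highest value at each of the 10 genes, from 20.3 at NEK6 to 51.2 at WDR1, was above it. The genes covered in shH2AJ only had shorter coverage, led by CCDC17 with 6.10 kb. KTN1, NNMT, SDR39U1, the p53 target BTG2, ENSG00000283782 and the interferon factor gene IRF1 (from a peak they share), TASOR2, ATL3 and PTP4A2 followed. Among the strongest genes of either list, coverage in shH2AJ was similar at some, smaller at others and larger at a few. EPAS1 was covered over 89.8 kb in shControl and 90.03 kb in shH2AJ, and TNFRSF21 over 78.4 and 80.5 kb. MYH9 went from 107.6 to 35.4 kb and GPRC5A from 29.3 to 5.23 kb. CLIC4 went from 57.3 to 76.9 kb, SCMH1 from 12.6 to 19.9 kb and CTPS1 from 15.8 to 20.1 kb. The highest shH2AJ value, 125.9, was at ANXA2, which encodes a membrane-binding annexin. After EPAS1 and TNFRSF21 came SLC2A1 (97.9), CTPS1, SCMH1 and SLFNL1 (79.8 each, from a peak they share), CLIC4 (79.7), and RPRD1B and TGM2 (74.8 each, from another shared peak).

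**Figure D3:**
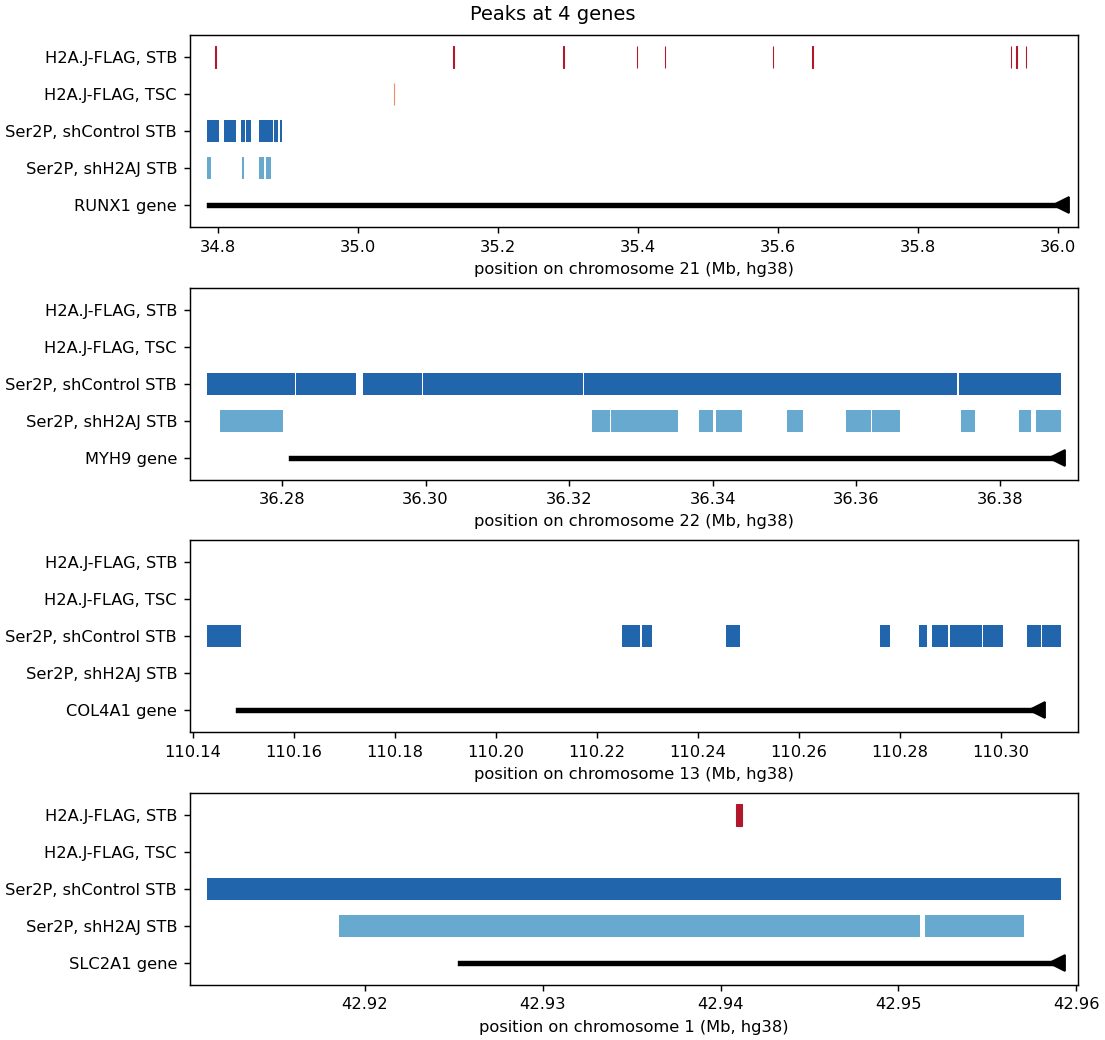
Horizontal bars mark the peaks of each of the 4 lists along RUNX1, MYH9, COL4A1 and SLC2A1, with position in Mb on hg38 on the horizontal axis, the gene in black and an arrowhead at its start. COL4A1 had 11 shControl Ser2P peaks and no shH2AJ peak, and RUNX1 had 10 STB FLAG peaks.

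In the shH2AJ list, set against random lists matched on gene length in the same way and also after the data were seen, 7 gene lists had an adjusted tail share under 0.05. Ribosomal protein genes had 33 of 79 with a peak against 5.55 expected, cytoskeleton genes 11 of 17 against 1.49, TSC and cytotrophoblast markers 8 of 25 against 2.11 and elongation genes 7 of 26 against 2.32. Senescence and p53 genes had 7 of 17 against 1.41, nutrient transport genes 7 of 21 against 1.92 and trophoblast transcription factors 6 of 22 against 1.82. These 3 had adjusted tail shares of 0.0710, 0.0890 and 0.0890 in shControl. Hypoxia genes, with 2 of 18 against 1.55, and H2A variants and replication-independent histones, with 2 of 10 against 0.689, did not pass in shH2AJ, at percentiles 66.7 and 91.2. Amnion markers had 4 of 12 against 1.02, with an adjusted tail share of 0.0775. Whether a list differed between shControl and shH2AJ is not shown by these counts.

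No gene list stood apart among the genes with a shControl peak and no shH2AJ peak once 22 lists were considered. Counts were set against 10000 random lists matched on shControl coverage. Some lists were too small to pass at any count. The pregnancy-specific glycoprotein and germ layer lists had 0 genes with a shControl peak. The fusion, steroidogenesis, pluripotency, cell cycle and imprinted lists had 2 each, and STB hormones and secreted factors had 4. For such lists the comparison does not decide either way. Ribosomal protein genes had the lowest percentile, 0.955, with 26 of 55 absent from shH2AJ against 34.0 expected. Senescence and p53 genes had 2 of 8 absent against 4.55, at percentile 2.92. MDM2, IGFBP3, CDKN1A, TP53I3, BAX and GADD45A had peaks in both lists, CDKN2A and SESN1 in shControl only. Hypoxia genes had 7 of 9 absent against 5.94, at percentile 78.1. These included the glycolysis genes ENO1, LDHA, ALDOA and PGK1, while SLC2A1 and ANKRD37 were in both lists. Nutrient transport genes had 2 of 9 absent against 3.80, at percentile 6.21. Of STB hormones and secreted factors, INHA, ADM and FSTL3 were absent and the activin subunit gene INHBA was covered over 24.3 kb in shControl and 8.14 kb in shH2AJ, while CRH was in shH2AJ only. Of other STB markers, FLT1, PHLDA2, TENT5A and TFPI2 were absent, 4 of 5 against 3.17, and PAPPA was covered over 21.5 kb in shControl and 2.998 kb in shH2AJ. TSC and cytotrophoblast markers had 3 of 11 absent (CDH1, EGFR and FZD5) against 4.37, and amnion markers 1 of 5 (TNC) against 1.69. Trophoblast transcription factors had 3 of 9 absent (MAFK, MSX2 and RXRA), while GATA3, TFAP2A, GRHL2, TBX3, ARID3A and HIF1A were in both lists. Cytoskeleton genes had 2 of 12 absent (FLNA and VIM), elongation genes 6 of 12, H2A variants and replication-independent histones 4 of 6, and replication-dependent histones 6 of 10. EVT markers had 1 of 5 absent, imprinted genes 2 of 2, inflammatory genes 2 of 3, and fusion, steroidogenesis, pluripotency and cell cycle genes 1 of 2 each. Some of these counts rest on the 2 kb flanks. Without flanks, trophoblast transcription factors had 0 of 6 absent, nutrient transport genes 0 of 6 and other STB markers 1 of 2. Shares rose in other lists, as in senescence and p53 genes, with 3 of 7, and ribosomal protein genes, with 29 of 50. FZD5 was counted through 6 bp of shControl coverage.

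**Figure D4:**
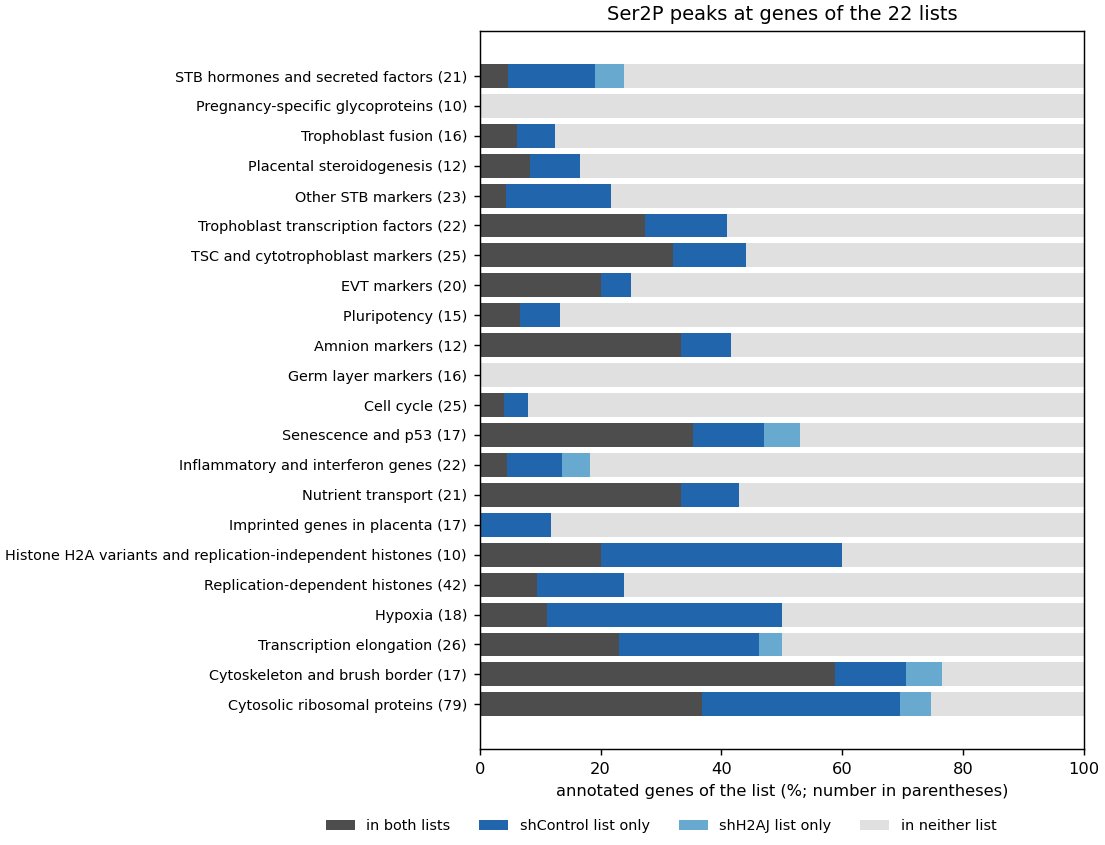
Stacked bars give the percentage of the annotated genes of each of the 22 lists with a Ser2P peak in both lists, in shControl only, in shH2AJ only or in neither, with the number of genes in parentheses. Ribosomal protein genes had 29 in both and 26 in shControl only, and the pregnancy-specific glycoproteins had none in either.

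The last comparison asked whether H2A.J-FLAG lay where elongating polymerase lay, and whether the genes it marked differed after knockdown. Of the STB FLAG peaks, 92 (1.77%, 1.45 to 2.16%) overlapped a shControl Ser2P peak, against a random mean of 41.7 with a range of 28 to 61. This was 2.21 times the random mean. For the shH2AJ list, 42 FLAG peaks (0.808%, 0.598 to 1.09%) overlapped, 2.72 times the random mean. Counted within 1 kb, the folds were 1.68 for shControl and 2.02 for shH2AJ. Random placements were not matched on gene starts, where the FLAG list and both Ser2P lists stood above random. The excess therefore does not show a link beyond shared location. At RUNX1, a FLAG peak at 34796696 to 34797161 lay within a shControl Ser2P peak at 34792453 to 34802614. At SLC2A1, the intronic FLAG peak lay within Ser2P peaks of both lists. Among genes with a shControl peak, 262 of 439 with a FLAG peak (59.7%) had no shH2AJ peak, and 2223 of 3485 without a FLAG peak (63.8%) had none. Random lists matched on shControl coverage gave 59.8%, with 95% of them between 56.0 and 63.6%, so the FLAG genes stood at percentile 46.9. In simulated lists, a loss raised by 5 percentage points at the FLAG genes was found in 68 of 100 simulations, and one raised by 10 points in 100. The difference from the matched mean, -0.158 percentage points, changed sign to 2.20 points without flanks around the genes and to 1.22 points with all annotated genes. It was -5.30 points with start windows, which left only 25 FLAG genes, -4.49 with lists of equal length and -3.65 without matching. It passed the percentile limits under none of these settings. The FLAG and Ser2P lists come from different cells, overexpressing and hairpin-carrying.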

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

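The alternatives with all annotated genes for peak locations, with FLAG peaks within 50 kb of a gene start and with gene lists at that distance were chosen after the data were seen. Over 14 results, 69 alternatives were run. Of these, 49 left the value within its interval, within 1.5 times the count or on the same side of its limits, 18 moved it and 2 changed its sign. No paired analysis was possible because each list pools its 2 samples, and for the same reason no replicate was left out. Depth is not given, so its effect on the number of peaks was not measured.

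For the STB FLAG peaks, windows of 3 kb raised the share at gene starts from 5.10% to 6.81%, since the windows are wider. The fold over random was then 1.83, against 3.37. All annotated genes gave 8.77% at starts and 32.2% between genes, since more of the genome is then annotated. The random means were 4.52% and 36.4%, so the fold at starts was 1.94. The peaks shared with TSC went from 46 to 28 with a reciprocal overlap of 50% and to 15 with the wider 50% of both lists. For Ser2P, a reciprocal overlap of 50% gave 812 shared shControl peaks and 1007 shH2AJ peaks without a partner. The upper 50% of both lists by value gave 665 shared, 1769 in shControl alone and 201 in shH2AJ alone, from lists shortened by construction. Lists of equal length gave 943 and 794 in the 2 lists alone, counts held near each other by construction, so they do not test the imbalance of 3557 against 411. By gene, a window of 1 kb around the start gave 389 genes in both lists, 948 in shControl only and 144 in shH2AJ only. The upper 50% of both lists gave 783 in both, and lists of equal length gave 899 in shControl only and 584 in shH2AJ only, also from a list shortened by construction. The excess loss at FLAG genes, -0.158 percentage points, changed sign to 2.20 without flanks (percentile 84.6) and to 1.22 with all annotated genes (percentile 75.2). It was -5.30 with start windows (25 FLAG genes, percentile 26.1), -4.49 with lists of equal length (percentile 6.57) and -3.65 without matching (percentile 4.89). The cause was not tested. Over its 8 alternatives the percentile ran from 4.89 to 84.6, within the limits in each. The number of gene lists passing stayed at 0 in 5 alternatives for FLAG genes and in 4 for genes without a shH2AJ peak. Up to 2 and 4 lists had an unadjusted tail share under 0.05.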

Other observations

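The motif tests, the tests of a single X copy and of region numbers, and the comparison of FLAG peaks near Ser2P genes were chosen only after the data were seen. FLAG peaks were somewhat more frequent near genes with Ser2P. Of the 3924 genes with a shControl Ser2P peak, 670 (17.1%) had an STB FLAG peak within 50 kb of their start, against 15.3% of all 19962 genes. Random lists of that size had 560 to 639. For the shH2AJ list, the count was 323 of 1664 genes (19.4%). These lists were not matched on gene density, and neighbouring genes share peaks, so the random range is too narrow. Of the 46 sites shared between STB and TSC, 2 lay at gene starts, of ALPK2 and EHBP1, chosen after their values were seen.

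The Ser2P list was shorter after knockdown, 1819 against 4868 peaks. Lower sensitivity of peak calling was assumed beforehand to leave the strongest shControl peaks nearly all found again, at 90% or more. A share below 75% was set beforehand as the bound for rejecting it as the cause. The measured share in the highest 10% was 70.99% (66.8 to 74.9%), below the bound by a narrow margin. Both figures, 90% and 75%, were assumed and not derived from lists selected by IDR. Such a list also depends on how well its 2 samples agreed, so this share does not settle whether lower sensitivity was the whole cause. Of 6 ways of counting, 5 of them added after this value was seen, the shares ran from 66.9 to 77.8% and all 6 had upper limits below 90%, while 3 had upper limits below 75%. In the other direction, 180 of 181 peaks (99.45%) in the highest 10% of the shH2AJ list overlapped a shControl peak, and 56.04% in the lowest 10%. A less sensitive list would give this, but so would a loss of part of the peaks, so it does not decide between them. Depth is unknown, and the lowest listed value was 13.5 in shH2AJ against 10.8 in shControl. Lower sensitivity therefore stays open as the cause of part or all of the difference. With 1 list per condition, no biological reading was tested against replicates. A loss centred on genes with H2A.J-FLAG was not seen, at percentile 46.9 of matched lists, although an excess of a few percentage points stays open.

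STB FLAG peaks were rare on chromosome X, with 12 peaks, or 0.0775 per Mb, against 1.88 on the autosomes. The ratio was 0.0412 (0.0213 to 0.0720), and it was 0.248 (0.192 to 0.316) for shControl Ser2P peaks. A single copy would give about 0.5 only if the number of peaks followed copy number. A selected list need not do so, and a single copy was therefore not excluded as a contributor. Base composition does not account for the shortage, since the 5 autosomes nearest to X in GC content had at least 1.90 peaks per Mb. The region numbers spanned 1.70 per Mb on X against at least 6.29 on the autosomes, so most of the shortage was there before the last selection, although 6.06% of the numbered span was kept on X against 13.4 to 19.3% on the autosomes. Mappability and an earlier filter by the authors were not tested, and no biological explanation was tested.

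Of the 10 motifs searched in the STB FLAG peaks, 7 occurred more often than in all 20 matched control sets and 1 less often. The AP-1 consensus occurred in 24.6% of peaks, 3.23 times the mean of matched control sets, of which the highest reached 8.38%, so base composition and width do not account for it. TEAD motifs stood at 2.05 times, ETS at 1.68, TFAP2 at 1.38, GATA at 1.17 and SOX at 1.09, POU5F1 (0.951) and CRE (1.20) lay within the range of the control sets, and the E-box stood below it at 0.709. The CTCF motif, of a factor bound in most cell types, stood at 3.42 times, so cutting at open chromatin irrespective of H2A.J stays open as a candidate explanation and cannot be told apart from H2A.J deposition at such sites without the empty-vector tracks, not analysed here. In TSC, AP-1 stood at 2.60 times, TEAD at 2.57 and CTCF at 6.90, the last from 10 of 192 peaks.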
